A study of Mus musculus with 25 samples.

How the data were processed

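The study holds 25 RNA-seq libraries of mouse oligodendrocyte precursor cells taken by laser capture microdissection, which cuts chosen areas from a tissue section under the microscope. How the areas were chosen is not given in the sources used here. Per the labels' protocols, cDNA was amplified with the Nugen RNA-Seq Ovation kit, libraries were made with Illumina TruSeq and Nugen reagents, reads were paired ends of 100 bp, and 3 samples were meant to share a lane. Per the submitters' processing notes, CASAVA 1.8.3, STAR 2.1.4a and HTSeq were used with the mouse genome build mm9. The values were deposited by the authors as RPKM, as the name of their table says. How RPKM was computed, to which reads it is scaled and which gene lengths were used are not given in the sources used here. Coordinates are not given, since the annotation at hand belongs to a later build.

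Amplification of small amounts of RNA enlarges the spread between libraries and drops transcripts of low abundance at random, so a gene near 0 in a library can be missing by chance. If RPKM was scaled to all reads of a library, a transcript that takes much of it lowers every other value in it. Rn45s, the ribosomal RNA precursor, took 73.4% of the RPKM sum in Control replicate 5 and 68% in Day 5 replicate 10. Without Rn45s their sums were 33982 and 39845, against group means of 19753 for controls and 38806 at Day 5. These sums show no such lowering. The values did not step in whole reads, the depth of each library is unknown, and no counting interval is given. Strand was not stated, so overlapping and antisense genes, and paralogs that share reads, are uncertain.

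Groups and replicate numbers came from the labels. The labels give no animal, batch or lane and do not tie captured samples to animals. Libraries of a group can share an animal, in which case p-values are too small, and they measure the spread between these samples, which may be technical.

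The table holds 23351 genes, 741 of them at 0 throughout, and 25 symbols that a spreadsheet had turned into dates were left unnamed. Genes with an RPKM of at least 1 in at least 7 libraries were kept, which left 4319. Values were taken as log2(RPKM + 1), a scale that understates the change of low genes. All 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (moderated tests with an intensity trend and robust variance estimates, two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Of 43 gene lists written before the data were examined (1130 entries, 1107 in the table, 491 kept), 38 had at least 5 tested genes. These were tested with camera at a preset correlation of 0.01, which compares a list with the other genes, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance.

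Library properties and cell type signals were compared with exact two-sided permutation tests, adjusted over the tests of each family, in Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6. Tested on simulated data with 200 changed genes among 4319, the Day 5 comparison recovered 4.4% of rises of 1, 52.4% of rises of 2, 90.4% of rises of 3 and 99.6% of rises of 4 on the log2 scale, and 1.6%, 12.8%, 16.8% and 25.6% of falls of those sizes, with 2.44% false calls. The simulated groups had no displacement shared by all genes. The rate of 2.44% thus need not hold for the real Day 5 comparison, where the median log2 change of all genes was 0.61. A list shifted by 1.5 was called in 10 of 10 runs.

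The genes named in the text follow a rule fixed together with the lists. In each comparison they are the 10 largest rises and 10 largest falls among called genes with a mean RPKM of at least 5 in either group, leaving out predicted models, or the 5 smallest p where none passed. A panel is always given (Pdgfra, Cspg4, Sox10, Olig2, Mbp, Gfap, Aqp4, Aif1, Cldn5, Snap25, Rtn4r, Inhba), as are the 3 members with the smallest p of each list that passed or held 3 called genes. Some genes that fall under this rule are not reported here. Genes named for passing under several scalings were chosen after their values were seen.

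The alternatives chosen together with these rules were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, upper-quartile scaling, quantile normalization, library weights, a replicate block, the number of detected genes as a covariate, leaving out libraries with few detected genes, a fit of the compared groups alone, a rank-sum test, a fold change of at least 2 and leaving out each library in turn. Added after seeing the data were scaling to the same sum without Rn45s, leaving out 3 libraries that resemble each other, and replicate numbers 1 to 6 against 7 to 10 as a covariate or apart. No column of the table was left unused.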

Results

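The series profiled RNA from oligodendrocyte precursor cells (OPC), the dividing glial cells from which myelin-forming oligodendrocytes arise, taken from mouse brain by laser capture microdissection. The 25 libraries fall into 3 groups by their labels: 10 controls, 8 from Day 5 of white matter stroke and 7 from Day 15. White matter stroke is an ischemic injury of the myelinated fibre tracts. The values are RPKM (reads scaled to gene length and to the reads of the library) as deposited, 1 column per library, and the number of reads behind them is unknown. The labels do not tie the libraries to animals, so p-values are too small if libraries share an animal.

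The libraries differed widely in how many genes they held. Genes at an RPKM of at least 1 numbered 2467 ± 890 (SD, n = 10) in controls, 4217 ± 1495 (SD, n = 8) at Day 5 and 2980 ± 1248 (SD, n = 7) at Day 15. Day 5 exceeded control by 1750 genes in a two-sided exact permutation test (p = 0.00654), which did not hold after Benjamini-Hochberg adjustment over 21 tests of library properties (adjusted p = 0.137). The sum of RPKM per library ran from 7583 to 127878. Rn45s, the ribosomal RNA precursor, took 73.4% of that sum in Control replicate 5 and 68.0% in Day 5 replicate 10. Nbas alone reached 10186 RPKM in Control replicate 4. Controls numbered 1 to 6 in their names held 10653 genes above 0 on average and those numbered 7 to 10 held 16719 (exact permutation p = 0.00476, adjusted p = 0.0429 over 9 tests), while the labels name no batch. The number ranges did not differ detectably in genes above 0 at Day 5 (15662 and 19064, exact p = 0.114) or Day 15 (12858 and 15090, exact p = 0.514). Controls held 2644 and 2202 genes at an RPKM of at least 1 in the same order (exact p = 0.481). The RPKM sum without Rn45s averaged higher in numbers 1 to 6 than in 7 to 10 in all 3 groups. The means were 44557 and 14916 at Day 15 (without overlap, exact p = 0.0286, adjusted p = 0.129). They were 52699 and 24913 at Day 5 (exact p = 0.0857, adjusted p = 0.257) and 23318 and 14406 in controls (exact p = 0.176, adjusted p = 0.257). None of these differences held after adjustment, but 0.0286 is the smallest exact p possible with 4 and 3 libraries.

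**Figure D1:**
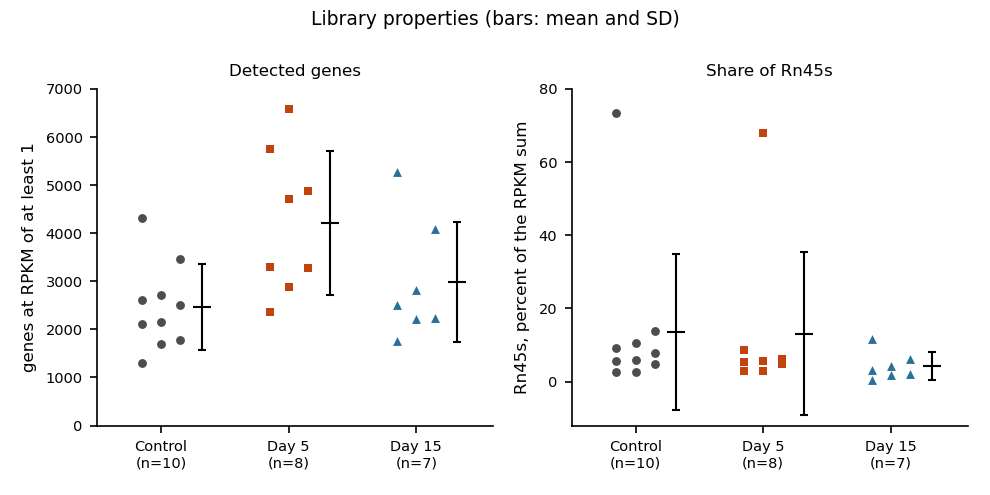
Genes at an RPKM of at least 1 (left) and the percent of the RPKM sum taken by Rn45s (right) in each library by group; each point is a library, and the bars give the mean and SD. Day 5 libraries averaged 4217 detected genes against 2467 in controls, and Control replicate 5 and Day 5 replicate 10 stand apart in Rn45s.

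Markers of other cell types were read in every library first, since a captured area can hold cells beside the target. The microglia signal, the mean log2(RPKM + 1) of 23 marker genes of the brain's resident phagocytes, was 1.15 ± 0.36 (SD, n = 10) in controls, 2.52 ± 0.74 (SD, n = 8) at Day 5 and 2.65 ± 0.75 (SD, n = 7) at Day 15. The signal of macrophages and other leukocytes, over 27 genes, was 0.68 ± 0.38, 2.34 ± 0.46 and 1.60 ± 0.59 in the same order. Exact permutation tests adjusted over 33 comparisons gave p = 0.000377 for both lists at Day 5, and at Day 15 p = 0.000566 for microglia and p = 0.00509 for macrophages. Within replicate numbers 1 to 6 the Day 5 differences were 1.52 for microglia and 1.60 for macrophages (adjusted exact p = 0.0381 for both, over 24 tests), and within 7 to 10 they were 1.31 and 1.84 (adjusted exact p = 0.0762 for both). At Day 15 they were 1.87 and 0.98 within 1 to 6 (adjusted exact p = 0.0381 and 0.0571) and 1.03 and 0.89 within 7 to 10 (adjusted exact p = 0.0762 for both). Before adjustment, both lists at both days had an exact p of 0.0286 within 7 to 10. That is the smallest p possible with so few libraries, so the adjusted values there do not speak against a difference. The signal of pericytes, smooth muscle and fibroblasts was higher at Day 5 than in controls by 0.43 (adjusted exact p = 0.0143), a call that did not hold after quantile normalization (adjusted exact p = 0.0671). Red blood cell genes were lower at Day 15 than at Day 5, with a difference of -0.17 (adjusted exact p = 0.0385). Their signal over 11 genes was near 0 in every group, at 0.19 in controls, 0.22 at Day 5 and 0.05 at Day 15. At such levels genes can be missing by chance. The OPC marker signal was 0.86 ± 0.28 in controls, 1.29 ± 0.46 at Day 5 and 1.00 ± 0.24 at Day 15, and no difference between these groups passed. After quantile normalization the Day 5 difference was -0.0169. After quantile normalization the myelin signal was also lower than in controls, by -0.75 at Day 5 (adjusted exact p = 0.00388) and -1.06 at Day 15 (adjusted exact p = 0.000424), and the neuronal signal by -0.38 at Day 5 (adjusted exact p = 0.00181). So were newly formed oligodendrocytes at Day 5, by -0.35 (adjusted exact p = 0.0344; 0.08 as deposited), and red blood cells at Day 15, by -0.20 (adjusted exact p = 0.00912). On the values as deposited these 5 differences did not pass.

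**Figure D2:**
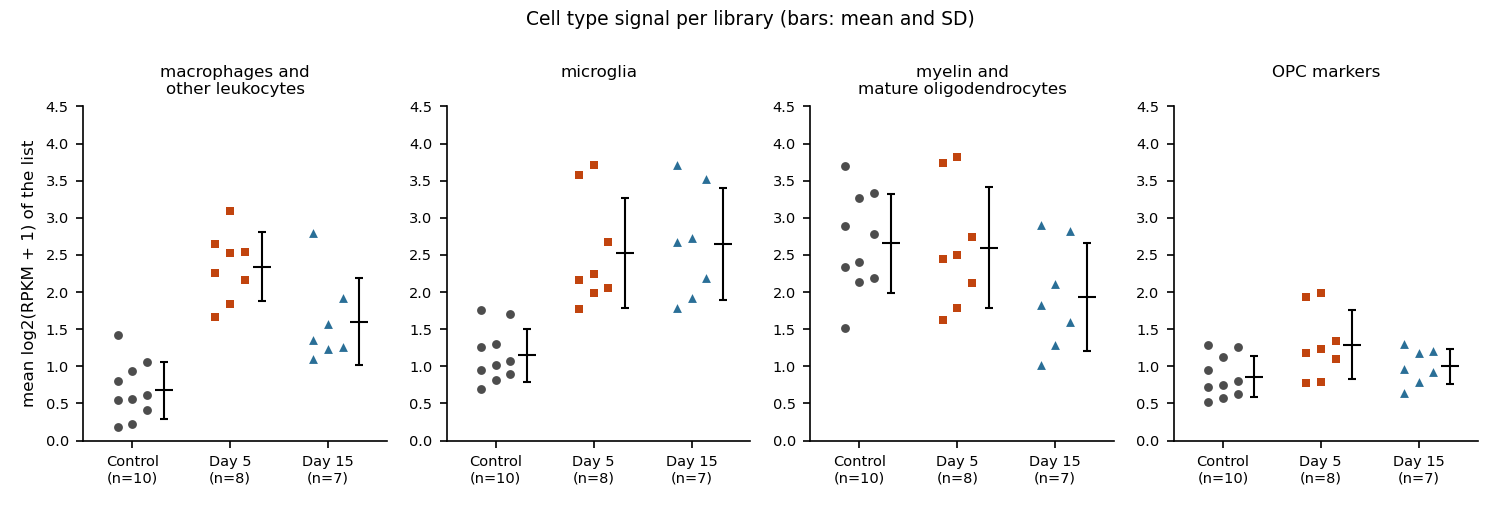
Mean log2(RPKM + 1) over the marker genes of 4 cell types in each library by group; each point is a library, and the bars give the mean and SD. All 8 Day 5 libraries, from 1.66 to 3.09, lie above the highest control, 1.42, in the macrophage signal, and the microglia signal is higher than in controls at both days.

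The first comparison asked what the captured cells express at Day 5 of white matter stroke against control. At Day 5, 11 of 15 tested macrophage genes, 11 of 29 lysosome genes and 7 of 12 lipid efflux genes rose (adjusted p = 0.0195, 0.193 and 0.183 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, averaged 485 ± 746 RPKM (SD, n = 8) at Day 5 and 6.58 ± 8.05 RPKM (SD, n = 10) in controls, a rise of 5.40 on the log2(RPKM + 1) scale (SE 0.83, limma adjusted p = 0.000136). Without Day 5 replicate 4, which held 2210 RPKM, the Day 5 mean of Lyz2 was 239 RPKM and the rise 4.89 (limma adjusted p = 0.000824). Spp1, which encodes the secreted protein osteopontin, rose by 5.17 (SE 0.81), Gpnmb, a glycoprotein of phagocytes, by 4.77 (SE 0.81), and Cd68, a lysosomal membrane protein of macrophages, by 3.54 (SE 0.63). Apoe, the lipid carrier, rose by 3.83 (SE 0.73) and Plin2, a coat protein of lipid droplets, by 3.95 (SE 0.76). Camk2n1, an inhibitor of a calcium-dependent protein kinase, was the sole gene that fell, by 1.92 (SE 0.52, limma adjusted p = 0.0255), from 7.77 ± 5.59 RPKM (SD, n = 10) to 1.11 ± 1.20 RPKM (SD, n = 8), a call lost without Day 5 replicate 10 (limma adjusted p = 0.0522).

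Of 4319 genes tested with limma, 261 passed at Day 5, 260 of them higher. The other named rises were Psap by 3.75, Apobec1 by 3.47, Ctss by 3.32 and Mpeg1 by 3.25. Of the 260 genes that rose, 180 had a control mean under 1 RPKM. The whole set of tested genes was displaced as well, with a median log2 change of 0.61 and 84.9% of genes above 0. That median was 0.10 after upper-quartile scaling, 0.15 after scaling to the same sum without Rn45s and -0.02 after quantile normalization. Under these 3 scalings 22 genes (18 higher, 4 lower), 33 genes (29 higher, 4 lower) and 20 genes (14 higher, 6 lower) passed. Passing as deposited and under all 3 were 15 genes, of which 14 were higher: Lyz2, Spp1, Gpnmb, Apoe, Cd68, Plin2, Apobec1, Il7r, Lgals3, AI607873, Lhfpl2, Man2b1, Nceh1 and Gla. Camk2n1 was the lower one. After quantile normalization the changes were 4.81 for Lyz2, 4.41 for Spp1, 4.06 for Gpnmb and -2.60 for Camk2n1. With the number of detected genes as a covariate, 0 genes passed and 447 had an unadjusted p under 0.05, and without Day 5 replicate 3 the count as deposited was 96. Within replicate numbers 1 to 6 and 7 to 10, which hold fewer libraries, 4 and 4 genes passed, and 398 did with the number range as a covariate.

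**Figure D3:**
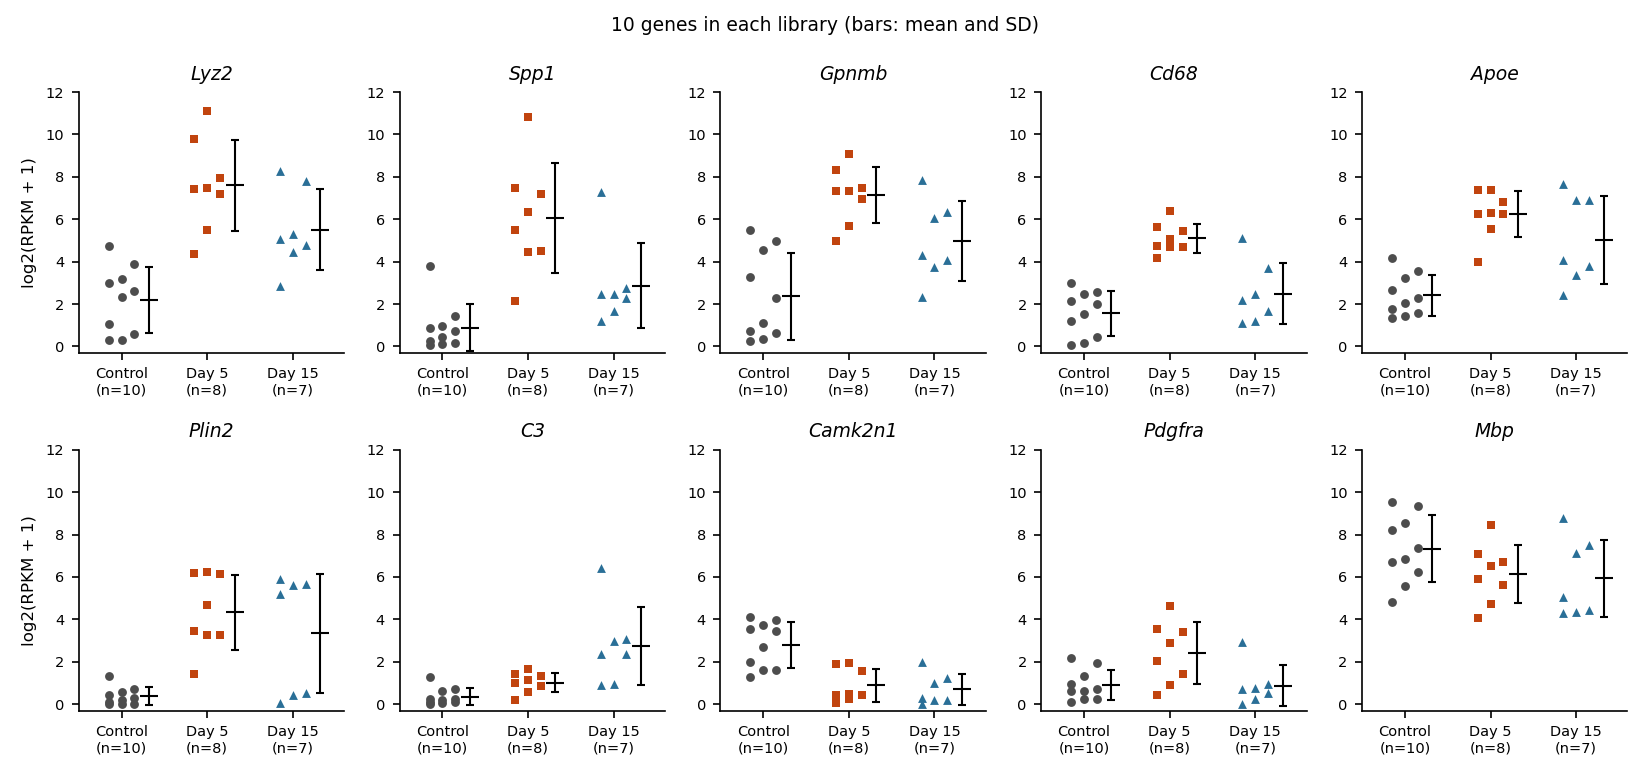
log2(RPKM + 1) of 10 genes in each library by group; each point is a library, and the bars give the mean and SD. Every Day 5 library holds more Cd68 (4.15 to 6.40) than any control library (0.08 to 2.98), while the groups overlap for Mbp and Pdgfra.

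Of the 38 gene lists tested at Day 5, 10 passed camera, 6 higher and 4 lower than the other genes. Among macrophage and leukocyte genes, 11 of 15 tested members rose and 4 did not pass (13 rose when adjusted over the list alone; camera adjusted p = 1.53e-14). This was the sole list that also passed with an estimated correlation (adjusted p = 0.0195). The macrophage signal, which averages genes of this same list and so restates the result, was higher by 1.66 in these libraries. The microglia signal was higher by 1.38. Lysosome and phagocytosis genes rose in 11 of 29 cases, 20 adjusted over the list alone, and none fell (camera adjusted p = 3.34e-10; adjusted p = 0.193 with an estimated correlation). They included Psap, the precursor of the saposins, Cd68 and Gpnmb. Lipid efflux genes and targets of the LXR nuclear receptors rose in 7 of 12 cases, 9 adjusted over the list alone (camera adjusted p = 5.76e-06; adjusted p = 0.183 with an estimated correlation), among them Abca1, the cholesterol exporter, by 2.74 (SE 0.71). Without Day 5 replicate 3 the call of Abca1 was lost (adjusted p = 0.0529). It was also lost under upper-quartile, sum and quantile scaling (limma adjusted p = 0.152, 0.112 and 0.115).

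Microglia genes rose in 7 of 22 cases, 9 adjusted over the list alone (camera adjusted p = 0.000985; adjusted p = 0.571 with an estimated correlation), with Ctss at 3.32, Tyrobp, a signalling adaptor of myeloid receptors, at 2.40 and Trem2, a lipid-sensing receptor that pairs with it, at 2.12. Complement genes rose in 5 of 13 cases, 7 adjusted over the list alone (camera adjusted p = 0.0263; adjusted p = 0.592 with an estimated correlation), with the integrin chain Itgb2 at 2.55 and the anaphylatoxin receptors C3ar1 at 2.97 and C5ar1 at 2.13. The calls of Trem2 (adjusted p = 0.0601) and C5ar1 (adjusted p = 0.0587) were lost without Day 5 replicate 1, and that of C5ar1 also without Day 5 replicate 3 (adjusted p = 0.0636). Under upper-quartile, sum and quantile scaling Ctss, Tyrobp, Trem2, Itgb2, C3ar1 and C5ar1 all lost their calls (limma adjusted p from 0.0600 to 0.204). Cytosolic ribosomal protein genes stood higher as a list (camera adjusted p = 0.00847; adjusted p = 0.843 with an estimated correlation), although 0 of 26 passed over all genes and 6 rose when adjusted over the list alone. Rpl7 at 1.54, Rpl32 at 1.85 and Rpl14 at 1.02 had the smallest p of that list. With the number of detected genes as a covariate, the complement list (adjusted p = 0.107) and the ribosomal list (adjusted p = 0.783) did not pass. The complement call was also lost without Control replicate 8 (adjusted p = 0.0520) and within replicate numbers 1 to 6 (adjusted p = 0.130). The ribosomal call was lost without Day 5 replicate 3 (adjusted p = 0.0743) or 6 (adjusted p = 0.0690), within 7 to 10 (adjusted p = 0.211), at a mean RPKM of at least 5 (adjusted p = 0.308) and with a pseudocount of 0.1 (adjusted p = 0.0522).

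Myelin genes stood below the other genes at Day 5 (camera adjusted p = 2.75e-06; adjusted p = 0.490 with an estimated correlation), with 0 of 27 tested members passing and a median log2 change of -0.13, which was -1.02, -0.95 and -1.06 under upper-quartile, sum and quantile scaling. Mobp, a structural protein of compact myelin, had a change of -1.72 (limma adjusted p = 0.140) and Cldn11, the tight junction protein of myelin, one of -1.35 (limma adjusted p = 0.250), while Evi2a had 1.19. The myelin signal differed by 0.23 within replicate numbers 1 to 6 and by -0.30 within 7 to 10 (adjusted exact p = 0.686 and 0.411). Neuronal genes stood lower as well, with 0 of 6 passing and a median of -0.14, or -0.73, -0.65 and -0.87 under the 3 scalings (camera adjusted p = 0.00847; adjusted p = 0.183 with an estimated correlation), with Snap25 and Camk2a at -0.996 and -0.803 and an adjusted p of 0.107 with the number of detected genes as a covariate. Fatty acid and myelin lipid genes were called lower (camera adjusted p = 0.00993; adjusted p = 0.592 with an estimated correlation), although their median was 0.29 and their mean 0.10, both below the median of all genes, and the median was -0.36, -0.29 and -0.44 under upper-quartile, sum and quantile scaling. Of its 18 members Sptlc2, a subunit of serine palmitoyltransferase, rose by 1.43, and Scd1 and Elovl5 had values of -1.62 and 1.39. Scd1 did not pass as deposited (limma adjusted p = 0.0817). It passed as lower under upper-quartile, sum and quantile scaling, with -2.39, -2.36 and -2.48 (limma adjusted p = 0.0345, 0.0338 and 0.0143). The call of Sptlc2 was lost under all 3 of these scalings (adjusted p from 0.311 to 0.440) and without Day 5 replicate 1, 3, 4 or 10 or Control replicate 1, 3, 4, 6, 8, 9 or 10 (adjusted p from 0.0538 to 0.108). Ion channels and receptors of the OPC were called lower in the same way (0 of 11 passing, median 0.08 and mean 0.08, the median -0.34, -0.27 and -0.46 under the 3 scalings, camera adjusted p = 0.0353; adjusted p = 0.592 with an estimated correlation), with Grik3, P2rx7 and Kcna2 at 1.02, 0.68 and -0.76 and P2rx7 at -0.0033 after quantile normalization. The ion channel call was lost without Control replicate 1 or 2 or Day 5 replicate 4, 6 or 9 (adjusted p from 0.0633 to 0.108), in either number range (adjusted p = 0.0590 and 0.207) and without the 3 resembling libraries, Day 5 replicate 4 and Day 15 replicates 5 and 6 (adjusted p = 0.0576). The fatty acid call was lost without Control replicate 9 (adjusted p = 0.0842), without the filter on low values (adjusted p = 0.235) and within replicate numbers 1 to 6 (adjusted p = 0.637). The neuronal call was lost within 7 to 10 (adjusted p = 0.420).

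None of the lineage and cell type genes always reported passed at Day 5. Pdgfra, the growth factor receptor that marks OPC, averaged 7.03 ± 7.84 RPKM (SD, n = 8) against 1.11 ± 1.21 RPKM (SD, n = 10), with a change of 1.498 (SE 0.53, limma adjusted p = 0.0681) that was 0.92, 0.98 and 0.755 under upper-quartile, sum and quantile scaling. Its Day 5 mean was 4.62 RPKM without Day 5 replicate 1. Cspg4, the NG2 proteoglycan, had 0.64 (0.21, 0.19 and 0.05 in the same order), Mbp -1.18 (-2.23, -2.14 and -2.28) and Sox10 0.43 (-0.28, -0.19 and -0.31). The astrocyte genes Gfap and Aqp4 had 1.27 (0.29, 0.37 and 0.36) and 1.09 (0.25, 0.32 and 0.22), and the microglial gene Aif1 had 0.64 (0.29, 0.30 and 0.12). Olig2, Cldn5, Rtn4r and Inhba were below the filter and not tested. Olig2 averaged 0.853 ± 0.701 RPKM (SD, n = 10) in controls, 0.526 ± 0.443 (SD, n = 8) at Day 5 and 0.231 ± 0.244 (SD, n = 7) at Day 15, or 0.145 without Day 15 replicate 7.

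The next comparison asked the same of Day 15 against control. Kcnj2, an inwardly rectifying potassium channel, rose by 2.49 (SE 0.52), Ly86, a partner of a Toll-like receptor homologue on immune cells, by 3.50 (SE 0.76), C3, the central complement component, by 2.37 (SE 0.53) and Ucp2, a mitochondrial carrier, by 3.23 (SE 0.72), each with a limma adjusted p of 0.0487. C3 averaged 15.6 ± 30.5 RPKM (SD, n = 7) at Day 15 and 0.332 ± 0.443 RPKM (SD, n = 10) in controls, or 4.09 without Day 15 replicate 2 and 0.209 without Control replicate 3. Microglia genes stood higher as a list in camera and myelin genes lower, but 0 members of either passed over all genes, and neither list passed with an estimated correlation (adjusted p = 0.0589 and 0.196).

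These 4 genes were the ones that passed among 4319, and 383 had an unadjusted p under 0.05, 326 of them higher. The median change of all genes was 0.17 as deposited, -0.02 after upper-quartile scaling, -0.10 after sum scaling and -0.03 after quantile normalization, with 9 genes (7 higher, 2 lower), 1 gene (lower) and 4 genes (2 higher, 2 lower) passing. No gene passed under all 4 scalings. C3, Ucp2 and, in the other direction, Camk2n1 (-2.10 as deposited, limma adjusted p = 0.0850) each passed under 3. The count was 2 or lower when any of 21 of the 25 libraries was left out, and 0 without Day 15 replicate 2, whose C3 value was 84.4 RPKM. Within replicate numbers 1 to 6 and 7 to 10 limma called 0 and 0 genes.

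Of 38 lists, 10 passed at Day 15, 8 higher and 2 lower, and none passed with an estimated correlation. Microglia genes gave a camera adjusted p of 2.86e-13 (adjusted p = 0.0589 with an estimated correlation), with 0 of 22 passing over all genes and 12 rising when adjusted over the list alone. Siglech, a lectin of microglia, had a change of 1.65 (limma adjusted p = 0.0850) and Olfml3 2.29. Macrophage genes followed (camera adjusted p = 3.61e-08; adjusted p = 0.136 with an estimated correlation), with 0 of 15 passing and 9 rising when adjusted over the list alone. Their leading members were Ptprc at 2.43, Lyz2 at 3.31 and Plin2 at 2.97, the last at 27.5 ± 26.4 RPKM (SD, n = 7). In the same libraries the microglia signal was higher than in controls by 1.501 and the macrophage signal by 0.93. These signals average genes of the same lists and so restate their result. For complement genes 1 of 13 rose, 5 adjusted over the list alone (camera adjusted p = 7.13e-06; adjusted p = 0.141 with an estimated correlation), with C3, C1qb at 2.28 and C3ar1 at 2.17. Lysosome genes had 0 of 29 passing, 7 adjusted over the list alone (camera adjusted p = 3.24e-05; adjusted p = 0.483 with an estimated correlation), with the cathepsins Ctsd at 3.37 and Ctsb at 3.08.

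Collagen and matrix genes also stood higher at Day 15 (camera adjusted p = 0.00220; adjusted p = 0.392 with an estimated correlation), with 0 of 14 passing, 1 adjusted over the list alone, and with Col3a1 at 1.58, Bgn at 1.60 and Fn1 at 1.74. Lipid efflux genes gave a camera adjusted p of 0.00275 (adjusted p = 0.392 with an estimated correlation; 0 of 12 passing, 4 adjusted over the list alone), with Apoe at 2.61 and Trem2 at 1.72. Cytokines and chemokines gave 0.00985 (adjusted p = 0.392 with an estimated correlation; 0 of 7 passing, 2 adjusted over the list alone), with Ccl3 at 1.44, Ccl5 at 1.502 and Spp1 at 1.99. Reactive astrocyte genes passed with a camera adjusted p of 0.0427 (adjusted p = 0.776 with an estimated correlation), with C3 as the 1 of 15 members that rose, and Ggta1 at 1.13 and Cd109 at 0.66. That list did not pass under upper-quartile scaling (adjusted p = 0.0674), sum scaling (adjusted p = 0.092) or quantile normalization (adjusted p = 0.0954). It was also lost with library weights (adjusted p = 0.0571), the detected-gene covariate (adjusted p = 0.0961), a mean RPKM of at least 5 (adjusted p = 0.380) and within replicate numbers 1 to 6 (adjusted p = 0.113). The same held without Control replicate 2, 4, 6, 7, 8, 9 or 10 or Day 15 replicate 2, 3 or 9 (adjusted p from 0.0505 to 0.223). The cytokine call was lost without Day 15 replicate 8 (adjusted p = 0.0699) and within replicate numbers 1 to 6 (adjusted p = 0.497).

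Myelin genes stood below the other genes at Day 15 with a median change of -0.89, or -1.32, -1.43 and -1.31 under the 3 other scalings (camera adjusted p = 6.02e-10; adjusted p = 0.196 with an estimated correlation), and 0 of 27 passed over all genes or adjusted over the list alone. Cldn11 had -2.43 (limma adjusted p = 0.236), Plekhh1 -1.49 and Aspa, which breaks down N-acetylaspartate in oligodendrocytes, -1.33. The myelin signal differed by -0.46 within replicate numbers 1 to 6 and by -1.06 within 7 to 10 (adjusted exact p = 0.452 and 0.0762). Within 7 to 10 the exact p before adjustment was 0.0286, the smallest possible with these libraries. Fatty acid and myelin lipid genes were lower too (median -0.63, or -0.92, -0.95 and -0.87 under the scalings; camera adjusted p = 0.00985; adjusted p = 0.550 with an estimated correlation; 0 of 18 passing), with Scd2 at -1.44, Elovl7 at -0.97 and Srebf1 at 1.57. This call was lost without Control replicate 9 (adjusted p = 0.0760), without the filter (adjusted p = 0.0669), at a mean RPKM of at least 5 (adjusted p = 0.0722) and within replicate numbers 1 to 6 (adjusted p = 0.457). Of the genes always reported, Aqp4, the water channel of astrocyte end-feet, had 2.23 (SE 0.63, limma adjusted p = 0.134), Mbp -1.39, Gfap 1.21, Cspg4 0.75, Aif1 0.18, Snap25 -0.20, Sox10 -0.05 and Pdgfra -0.03, and none passed. Under upper-quartile, sum and quantile scaling Mbp had -1.87, -2.03 and -2.09 and Gfap 0.81, 0.64 and 0.63. In the same order Snap25 had -0.56, -0.66 and -0.71, Sox10 -0.26, -0.37 and -0.45, and Pdgfra -0.21, -0.25 and -0.18, again without passing.

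The last comparison set Day 15 against Day 5, which also tests whether the changes against control differ. Macrophage genes stood lower at Day 15 (median -1.47, or -1.12, -1.19 and -0.92 under upper-quartile, sum and quantile scaling; camera adjusted p = 0.0305), and microglia genes (camera adjusted p = 0.00570) and astrocyte genes (camera adjusted p = 0.0305) stood higher relative to the other genes. With an estimated correlation each had an adjusted p of 0.902. The call of the astrocyte list was lost after quantile normalization (adjusted p = 0.0510), that of the macrophage list with the number of detected genes as a covariate (adjusted p = 0.109) and within replicate numbers 1 to 6 (adjusted p = 0.218), and that of the microglia list within 7 to 10 (adjusted p = 0.673). At a mean RPKM of at least 5 all 3 calls were lost (adjusted p = 0.0641 for astrocytes, 0.0584 for macrophages and 0.340 for microglia). That of the astrocytes was lost also without the filter (adjusted p = 0.110) and with the detected-gene covariate (adjusted p = 0.0571). The macrophage call was also lost without Control replicate 2, Day 5 replicate 3 or 4, or Day 15 replicate 3, 6, 7, 8 or 9 (adjusted p from 0.0514 to 0.114). The astrocyte call was lost in either number range (adjusted p = 0.122 and 0.0819) and without Day 5 replicate 4 or Day 15 replicate 2, 3, 6 or 7 (adjusted p from 0.0521 to 0.0942). The microglia call was lost without Day 15 replicate 2 (adjusted p = 0.0696). Lgals3, a lectin of phagocytes, had a change of -2.45 (SE 0.56), Ms4a7 one of -2.41 (SE 0.62) and Cd68 one of -2.60 (SE 0.69), each with a limma adjusted p of 0.183. Of the microglia genes, Siglech had 1.01, Sall1, a transcription factor of microglia, 1.57 and Cd53 -1.48, and of the astrocyte genes Slc1a2, a glutamate transporter, 1.66, Aqp4 1.15 and Acsbg1 0.78.

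No gene passed limma between the days, where the smallest adjusted p was 0.183 and 633 genes had an unadjusted p under 0.05, 599 of them lower at Day 15. An exact rank-sum test also called 0 genes, and without Day 15 replicate 5 limma called 8, all lower. The genes with the smallest p beside Lgals3 were Sp3 at -2.44, Il17ra at -2.30, Il7r at -1.89 and Gpr137b-ps at -2.09. The median change of all genes was -0.44 as deposited, -0.12 after upper-quartile scaling, -0.23 after sum scaling and 0.00 after quantile normalization. Against that background the microglia median of 0.08 (0.38, 0.18 and 0.38 under the other scalings) and mean of 0.11 were above, and the astrocyte median of -0.06 and mean of 0.10 differed in sign, with a median of 0.36, 0.19 and 0.28 under the 3 other scalings. No microglia, macrophage or astrocyte member passed over all genes; adjusted over the list alone, 8 macrophage genes were lower and 1 higher. The microglia signal differed by 0.13 (adjusted exact p = 0.935), by 0.36 within replicate numbers 1 to 6 and by -0.28 within 7 to 10 (adjusted exact p = 0.623 and 0.363), and the astrocyte signal by 0.02 (adjusted exact p = 0.981). After quantile normalization the microglia and astrocyte signals differed by 0.42 and 0.26 (adjusted exact p = 0.0848 and 0.194). The macrophage signal was lower at Day 15 by -0.74 (adjusted exact p = 0.0853 as deposited; by -0.48, adjusted exact p = 0.0392, after quantile normalization), and within the 2 number ranges it differed by -0.62 and -0.95 (adjusted exact p = 0.320 and 0.125). Of the panel, Pdgfra had -1.53 (limma adjusted p = 0.246), and Aif1 -0.46, Snap25 0.80, Sox10 -0.48, Mbp -0.20, Cspg4 0.10 and Gfap -0.06, of which Mbp and Gfap were above 0 under the 3 other scalings, Sox10 under upper-quartile scaling and Aif1 after quantile normalization.

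The changes at both days were set against each other across genes, which are not independent replicates. Pearson's r over 4319 genes was 0.52 and the covariance 0.234. Both comparisons use the same 10 controls. In 100 simulations without any change, the deviations of the 25 libraries from their group means were shuffled across all libraries. Both simulated days were then set against the same simulated controls. This gave a mean r of 0.44 (highest 0.60) and a mean covariance of 0.112 (highest 0.171), leaving a difference in covariance of 0.121. The simulated controls were drawn from all 3 groups, so these values need not match what the 10 real controls alone would give. Deviations from fitted group means are also somewhat smaller than the true spread, and they were not enlarged here. The simulated covariance is thus somewhat too low and the difference of 0.121 somewhat too large. With 5 real controls for each day, r was 0.25 and 0.24 and the covariance 0.136 and 0.133. Of the 260 genes that rose at Day 5, 0 also passed at Day 15, where independent lists would share 0.242, so this count cannot tell overlap from chance.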

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

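The rule that singled out the libraries below did not depend on the data, while the tests of explanations and the regroupings of libraries were all written after the results they bear on had been seen.

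In 44 of 264 groups of values 1 library stood far from the others of its group. Chance singles out about 1 in 20 groups, or 13.2 here, if values are normal and groups independent. The groups share the same 25 libraries and many values lie near 0, so the excess alone does not mark unusual libraries. Rn45s took 73.4% of the RPKM sum in Control replicate 5 (next control 13.7%) and 68.0% in Day 5 replicate 10 (next 8.61%), and the 10 highest genes other than Rn45s took 50.9% in Control replicate 4 (next 18.4%). The signal of newly formed oligodendrocytes was 2.13 in Day 15 replicate 3, that of ependymal cells and choroid plexus 0.81 in Control replicate 6 and 0.63 in Day 5 replicate 4, and that of red blood cells 0.20 in Day 15 replicate 5.

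Of 219 groups of values of single genes, 37 held such a library, and it was the highest of its group each time. In controls, in RPKM, these were Bgn at 3.50, Ccl3 at 1.148, Kcna2 at 44.6 and Trem2 at 2.99 in replicate 1, and Aif1 at 3.35, Rpl14 at 1.57 and Sox10 at 94.7 in replicate 2. Control replicate 5 had C5ar1 at 0.843, Ctss at 36.7, Gfap at 335.4, Grik3 at 1.018, Spp1 at 12.8, Tyrobp at 6.29 and Ucp2 at 16.0, and Control replicate 7 had Acsbg1 at 2.70, Mpeg1 at 123.9, Siglech at 0.758 and Sptlc2 at 2.57. Cspg4 was at 9.78 in Control replicate 8 and Elovl7 at 26.5 in Control replicate 9. At Day 5, Grik3 was at 41.2 in replicate 1 and Ggta1 at 88.4 in replicate 3. Day 15 replicate 5 had Cspg4 at 25.0, Ctss at 1377, Il7r at 5.04, Itgb2 at 21.5, Lgals3 at 7.51, Ms4a7 at 12.8, Pdgfra at 6.52 and Spp1 at 153.2. The other Day 15 values were C3 at 84.4 in replicate 2, C5ar1 at 97.8 and Elovl5 at 6.63 in replicate 3, Kcna2 at 27.3 and Snap25 at 56.0 in replicate 6, Mobp at 88.0 in replicate 7 and Kcnj2 at 74.3 in replicate 9.

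Lists of microglia (camera adjusted p = 0.00570), astrocytes (0.0305) and macrophages (0.0305) differed between Day 15 and Day 5, and none of the 3 passed with an estimated correlation.

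Nearly all genes called at Day 5 were higher than in controls. Scaling stays open: of the genes at an unadjusted p under 0.05, 98.7% were higher as deposited and 73.2%, 78.01% and 55.01% after upper-quartile, sum and quantile scaling, but centring the libraries evens such a split by itself. Of the called genes 18 of 22, 29 of 33 and 14 of 20 were still higher under these scalings. Of the 260 genes that rose as deposited, 18, 29 and 14 still passed. All 260 kept changes above 0, with a median of 1.95 as deposited (median SE 0.54) and 1.30 after quantile normalization (median SE 0.48). Their choice nearly fixed this sign, since the smallest of these rises was 0.91 as deposited. Quantile normalization moved the median change of all genes only from 0.61 to -0.02. A lower yield of falls may account for part, since 12.8% of simulated falls of 2 were recovered against 52.4% of rises of 2. Part of that gap was built in, since simulated values below 0 were set to 0 and falls of low genes were thus smaller than 2. A true excess of rises was not tested apart from these and stays open.

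Genes of macrophages and microglia were higher at Day 5. Scaling alone is argued against, since after quantile normalization the macrophage signal was still higher by 1.30 and the microglia signal by 0.80 (adjusted exact p = 0.000424 for both). As deposited they were higher by 1.66 and 1.38. Such cells inside the captured areas stay a candidate source that no value here decides: that 31 of the 37 tested members of both lists (83.8%) changed by more than the median gene restates the pattern. The abundant genes Lyz2 and Ctss averaged 485 and 97.2 RPKM (239 and 60.3 without their highest libraries, Day 5 replicates 4 and 3), and 7 of 22 tested microglia and 6 of 15 macrophage members also belong to another list. Expression by the precursor cells themselves cannot be told apart from this in bulk libraries, where the precursor marker signal differed by -0.0169 after quantile normalization, and how the areas were chosen is not in the labels.

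Day 5 replicate 4 and Day 15 replicate 5 resembled each other more than any other pair (Spearman correlation across genes 0.896, next 0.786), and 4.75% of their genes above 0 were found in 1 of them only (next pair 12.9%). The same library under both names is argued against by 16 of their 18 highest genes, which differed by more than 4-fold, such as Ctsd at 43.1 and 4876 RPKM. A large number of detected genes is argued against by the other 5 pairs with at least 19000 genes above 0, whose highest correlation over genes below 1 RPKM was 0.572, against 0.797 in this pair. Reads carried from one library into the other cannot be told apart from other causes, since the median log2 ratios of low genes, -0.0783 and 0.304 by direction, lay below those of another library, 0.116 and 0.341. Lanes are not in the labels, and no biological explanation was tested.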

How the results depend on the processing

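Scaling to the same sum, leaving out the resembling libraries, the replicate number ranges and, for lists, both filter settings were chosen after seeing the data; the other alternatives were not. No named gene that passed as reported changed sign under another setting. The signs of the other called genes were followed only under the 3 scalings. No list that passed changed its direction relative to the other genes, but the median changes of 3 such lists did change sign with scaling: fatty acid and ion channel genes at Day 5 and astrocyte genes between the days. Of named genes that had not passed, 65 values changed sign, 38 under other settings and 27 when 1 library was left out, and 0 of them passed there. The median change of all genes also changed sign with scaling at both days. The Day 5 gene count of 261 became 553 with a pseudocount of 0.1, 24 without the filter, 119 at a mean RPKM of at least 5, 22 with upper-quartile scaling, 33 with sum scaling, 20 with quantile normalization, 597 with library weights, 0 with detected genes as a covariate (447 at an unadjusted p under 0.05), 147 without the low-detection library (Control replicate 3), 398 with the number range as a covariate, 4 in replicate numbers 1 to 6, 4 in 7 to 10 and 418 by the exact rank-sum test. The Day 15 count of 4 became, in the same settings, 38, 0, 11, 9, 1, 4, 29, 1, 0, 5, 0, 0 and 0, and 2 in a fit of the compared groups alone. Fewer libraries enter the number ranges and 22610 genes are tested without the filter; for the other settings the cause was not tested. Lists passing at Day 5 went from 10 to 1 with an estimated correlation and 22 by fry, and at Day 15 from 10 to 0 and 3. All 22 were higher at Day 5. They included the 6 lists that camera called higher but none of the 4 it called lower (fry adjusted p from 0.466 to 0.876). Since fry does not set a list against the other genes, the median change of 0.61 over all genes counts toward these rises. At a mean RPKM of at least 5 they were 8 and 6 (7 and 6 of them shared with those reported), and without the filter 14 and 10 (9 and 9 shared). Between the days they went from 3 to 0 and 0, to 0 by camera at a mean RPKM of at least 5, 6 without the filter (2 shared), 6 with weights, 1 with the detected-gene covariate, 6 without the 3 resembling libraries and 5 with the number range. Cell type signals passing went from 6 to 11 after quantile normalization, and r stayed between 0.522 and 0.585 in 6 settings.

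Replicate numbers did not pair the libraries: correlations of 20 same-numbered pairs ran from -0.06 to 0.08, 0 of them over 0.1, and 2 of 25 libraries correlated best with their own number. With a replicate block 499 genes passed at Day 5, 4 at Day 15 and 0 between the days, where 6 lists passed.

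Leaving out each library gave 96 to 418 genes at Day 5, with 96 and 134 without Day 5 replicates 3 and 1, 154 without Day 5 replicate 10, 135, 138, 147, 152, 154 and 170 without Control replicates 9, 10, 3, 6, 4 and 1, and 418 without Day 5 replicate 7. Day 15 counts ran from 0 to 6: 6 without Day 15 replicate 8, 1 without Day 15 replicates 7 and 9, Day 5 replicate 9 and Control replicates 1 and 5, 2 without Day 15 replicate 6 and Day 5 replicate 6, and 0 without Day 15 replicate 2, Day 5 replicates 1, 4, 7, 8 and 10 and Control replicates 2, 3, 4, 6, 7, 8, 9 and 10. Between the days they ran from 0 to 8, with 8 without Day 15 replicate 5 and 1 without Day 5 replicate 7. Lists ran from 8 to 11 at each day against control and from 1 to 5 between the days, with 1 without Day 15 replicates 3 and 7 and Day 5 replicate 4, and 5 without Day 5 replicates 7 and 8. Of the values of single named genes under other settings, 1251 kept their side of the threshold, 124 lost the call and 46 gained it; of the lists, 283 kept and 35 lost it. Depth is unknown, so no bound can be set on genes listed near 0.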

Other observations

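The groups below were fixed beforehand, while the genes named in them were chosen after their values were seen, and the regroupings of libraries were also run after the results had been seen.

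A few members of lists that did not pass rose at Day 5 in limma. Igf1, a growth factor for oligodendrocytes, rose by 2.62 (SE 0.63, limma adjusted p = 0.0120), and Il6st, the shared receptor chain of the interleukin-6 family, by 2.13 (SE 0.61), making 2 of 14 tested growth factor and receptor genes (3 adjusted over the list alone; camera adjusted p = 0.907). The antioxidant enzymes Prdx6 and Gpx1 rose by 2.47 and 1.84, 2 of 17 oxidative stress genes (camera adjusted p = 0.974). In the TGF-beta, activin and BMP list, Smad1 and Acvr1 rose by 1.49 and 1.10, 2 of 13 genes, 5 adjusted over the list alone (camera adjusted p = 0.313). Hif1a, the oxygen-regulated transcription factor, rose by 1.96 in the hypoxia list (1 of 12 genes, 4 adjusted over the list alone; camera adjusted p = 0.836). Every one of these changes has to be read beside the median of 0.61 over all genes, none of these 7 genes passed at Day 15, and none was among the 15 that passed under all 4 scalings at Day 5.

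OPC marker genes had a median change of 0.70 at Day 5 (0.18, 0.22 and 0.08 under upper-quartile, sum and quantile scaling), with 12 of 12 tested members above 0 (8 of 12 under each of these scalings), 0 passing and 2 rising when adjusted over the list alone (camera adjusted p = 0.699). Cell cycle genes had a median of 0.82 (0.39, 0.38 and 0.16), with 0 of 7 passing (camera adjusted p = 0.599), and interferon response genes one of 0.55 (-0.02, 0.03 and -0.02), with 1 of 29 passing (camera adjusted p = 0.709).

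Regrouping the libraries at random tested whether chance alone gives such counts. In 100 splits, the real one included, 1 gave as many genes as the real 261 at Day 5 (highest other 123) and 1 gave as many lists as the real 10 (highest other 9). At Day 15, 1 of 100 gave the real 4 genes (highest other 1) and 1 of 100 the real 10 lists (highest other 8). For these 4 counts random regrouping thus reached the real value in a share under 0.05. The splits treat libraries as independent and ignore the replicate number ranges, so they do not exclude chance if libraries share an animal or a batch. The Day 15 gene count was also 0 when any of 14 libraries was left out. Between the days 10 of 100 splits gave at least the real 3 lists (highest other 6), so chance cannot be excluded for that count. The real count of genes by limma was 0 (633 at an unadjusted p under 0.05, 0 by the exact rank-sum test; highest other 2), which all 100 splits reach by construction, so the splits say nothing about it.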
